A study of Rattus norvegicus with 12 samples.

How the data were processed

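The deposited data are 12 RNA-seq libraries from rat preoptic area, 1 file each, from males and females given vehicle or zebularine on postnatal days 0 and 1 and collected on postnatal day 2. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made by a standard Illumina procedure. The vehicle was saline with 0.1% of a solvent that the labels spell DNMSO. TopHat, an aligner, is named in the submitters' processing notes without a version. The read counter, genome build and gene annotation are not given in the sources used here, nor is whether counting used strand, so reads of overlapping, antisense or near-identical genes may be shared between them. Groups and replicate numbers come from the sample titles.

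The authors deposited RPKM, reads per kilobase of gene model scaled to library size, for 29516 Ensembl gene identifiers in each file. The design had allowed for either counts or RPKM, and the test set for RPKM was used. The low values show whole reads: for each of the 23427 genes above 0 in at least 1 library, the values are whole multiples of 1 step once scaled by library depth, within 1e-05 of a read at low counts and 0.002 at high counts. For 1386 of these genes, above 0 in 1 library only, this holds trivially. The steps gave the reads assigned to genes, from 15851598 to 30474857 per library (a 1.92-fold range), and the gene model lengths. Of the lengths of genes with over 10 reads on average, 48.0% are divisible by 3. The RPKM denominator matched the reads assigned to genes. Replicate libraries differed beyond sampling noise, with a chi-square per degree of freedom from 5.94 to 22.0, so none was counted as a duplicate.

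Genes with at least 0.5 RPKM in at least 3 libraries were kept, 16310 in all. log2(RPKM + 0.5) was fitted with limma (version 3.58.1, R 4.3.3; eBayes with trend, not robust) as 4 group means over 12 libraries, with no further scaling. The 7 comparisons were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are on the log2(RPKM + 0.5) scale, which understates changes of low genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The 7 comparisons with their tests, the first list of alternatives, the rule for named genes and the gene lists were fixed before the data were examined.

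The fit was tested on simulated data made from the real genes' levels and library sizes, in 5 sets with 200 changed genes each. The changed genes were drawn only from genes above a minimum mean number of reads, and were changed alike in both sexes. For the zebularine effect over both sexes, 73.8%, 85.5% and 96.4% of genes changed 1.5-fold, 2-fold and 4-fold were found among 16310 genes. For females the shares were 57.4%, 76.4% and 93.0%, and for males 55.3%, 75.5% and 94.2%. False calls made up 5.34%, 5.87% and 4.96% of the calls, in that order. Real libraries share structure that these draws lack, so real recovery can be lower. Recovery of genes with fewer reads than that minimum was not measured.

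Named genes follow a rule: where 10 or more genes pass, the genes with the largest log2 change whose compared groups do not overlap, and otherwise those with the smallest p in each direction, at a mean of at least 1 RPKM in a compared group. Because the files do not pair identifiers with symbols, at most 2 genes per direction and comparison are named. ENSRNOG00000015550 and the others named in several comparisons were each picked by the rule in at least 1. The gene name table used here, of RefSeq genes of assembly GRCr8, matched 0 of the 29516 identifiers. The 31 gene lists fixed beforehand, the check of sex labels by sex-linked genes and the values of genes named by symbol in the rule are therefore not analysed here.

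The alternatives were median-ratio scaling, quantile normalization, pseudocounts of 0.1 and 1, no filter on low values, a filter of 1 RPKM, robust limma, array weights, a fit with only the compared groups, blocks on the replicate number and on a number in the file names, an adjusted p threshold of 0.10, and leaving out each library. Added after seeing the data were limma-voom on recovered reads, thinning all libraries to the shallowest, removing each library's trend with gene length, and a covariate for the first component of the within-group residuals. The simulation with residual SDs, the covariance from the vehicle female spread, the ranking of genes by their mean over all libraries, and the tests of equal medians, of shared variation among genes and of a single library were also added then.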

Results

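RNA was sequenced from the preoptic area of newborn rats, a forebrain region that differentiates by sex around birth. Males and females received zebularine, a cytidine analogue that inhibits DNA methyltransferases (DNMT), or vehicle on postnatal days 0 and 1, and tissue was taken on postnatal day 2. The 12 libraries form 4 groups of 3: vehicle females, zebularine females, vehicle males and zebularine males. Reads assigned to genes ran from 15851598 in zebularine male replicate 2 to 30474857 in zebularine male replicate 1. Vehicle libraries averaged 25801205 reads and zebularine libraries 22363439 (two-sided exact permutation p = 0.173). At the median gene model length, 3 reads correspond to between 0.0433 and 0.0832 RPKM (reads per kilobase of gene model, scaled to library size), which sets the lowest level that could be told from 0, for counting error only. Genes carry only Ensembl identifiers in the files, which do not pair them with symbols, so genes are described by identifier, level and response. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

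Males and females given vehicle were compared first, to describe the sex difference without treatment. Of 16310 genes tested, 2 were higher in females and none higher in males. Without symbols, it could not be checked whether genes of the Y chromosome were among those tested. The lack of genes higher in males, here and in the other comparisons between the sexes, is therefore not read as biology. ENSRNOG00000037911 was abundant in vehicle females, at 50.7 ± 8.68 RPKM (SD, n = 3), and close to the floor in vehicle males, at 0.146 ± 0.00550 RPKM (SD, n = 3), which corresponds to between 4 and 5 reads per library. The male minus female difference was -6.29 ± 0.13 (SE) on the log2(RPKM + 0.5) scale, with an adjusted p of 5.89e-10 by limma. ENSRNOG00000006186 was higher by a smaller step, at 63.1 ± 3.83 RPKM in vehicle females and 39.1 ± 1.70 RPKM in vehicle males (SD, n = 3), a log2 difference of -0.68 ± 0.06 (SE, limma adjusted p = 0.000800). Among genes higher in males, the smallest p belonged to ENSRNOG00000038478, at 9.12 ± 1.71 against 6.14 ± 0.277 RPKM (SD, n = 3), which did not pass (limma adjusted p = 1.00). At an unadjusted p under 0.05, limma counted 154 genes with male higher and 186 with female higher, 2.08% of those tested. Chance alone puts a share of about 0.05 of tested genes under that threshold, so this count lay below it. For a gene of median precision the 95% interval of a fold reached 1.19-fold to either side. The count was 5 with no filter on low values, 1 of them higher in males, and 1 with only the groups compared in the fit, where ENSRNOG00000006186 no longer passed (limma adjusted p = 0.0830, from 0.000273 to 0.162 over the alternatives).

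Zebularine was then compared with vehicle over both sexes, the comparison with the most libraries, 6 against 6. In this comparison 65 genes were higher under zebularine and 1 was lower. The 65 genes rose by a median of 1.83-fold, from 1.25-fold to 8.27-fold, and 21 of them at least 2-fold. The top of that range, ENSRNOG00000015550, was carried by females, with a log2 change of 5.44 in females and 0.66 in males (limma unadjusted p = 0.369 in males). Genes of low expression were over-represented among them: their median vehicle level was 1.27 RPKM against 8.07 RPKM for all genes tested, and 28 of the 65, or 43.1%, lay under 1 RPKM in vehicle libraries, where 12.6% of all tested genes lay (two-sided Fisher's exact p = 9.77e-10, odds ratio 5.30). At 10 RPKM or more lay 5 of the 65. Ranked by the mean over all 12 libraries, which does not favour genes that start low, 34 of the 65 belonged to the 4078 genes with the lowest mean (two-sided Fisher's exact p = 2.22e-06, odds ratio 3.31). These tests treat genes as independent, which they are not. ENSRNOG00000002217 rose from 0.251 ± 0.174 to 6.23 ± 4.02 RPKM in females and from 0.246 ± 0.0966 to 3.73 ± 0.0462 RPKM in males (SD, n = 3), with an average log2 change of 2.75 ± 0.26 (SE, limma adjusted p = 0.00351). ENSRNOG00000015411 rose from 0.800 ± 0.0653 to 3.43 ± 1.63 RPKM in females and from 0.315 ± 0.0604 RPKM (SD, n = 3) to 2.92, 2.23 and 2.35 RPKM in males, a log2 change of 1.69 ± 0.17 (SE, limma adjusted p = 0.00416). Both were higher in 6 of 6 treated libraries than in any vehicle library of the same sex, which the rule that named them required. The 1 lower gene, ENSRNOG00000043790, fell by 0.94 on the log2 scale (SE 0.16, limma adjusted p = 0.0383), from 4.15 ± 1.25 to 1.49 ± 0.300 RPKM in females and from 3.72 ± 0.104 to 2.19 ± 0.836 RPKM in males (SD, n = 3), on between 2 and 11 reads per library. With the libraries thinned to equal depth its log2 change was -0.37 and did not pass (limma adjusted p = 0.680, and from 0.0179 over the alternatives).

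**Figure D1:**
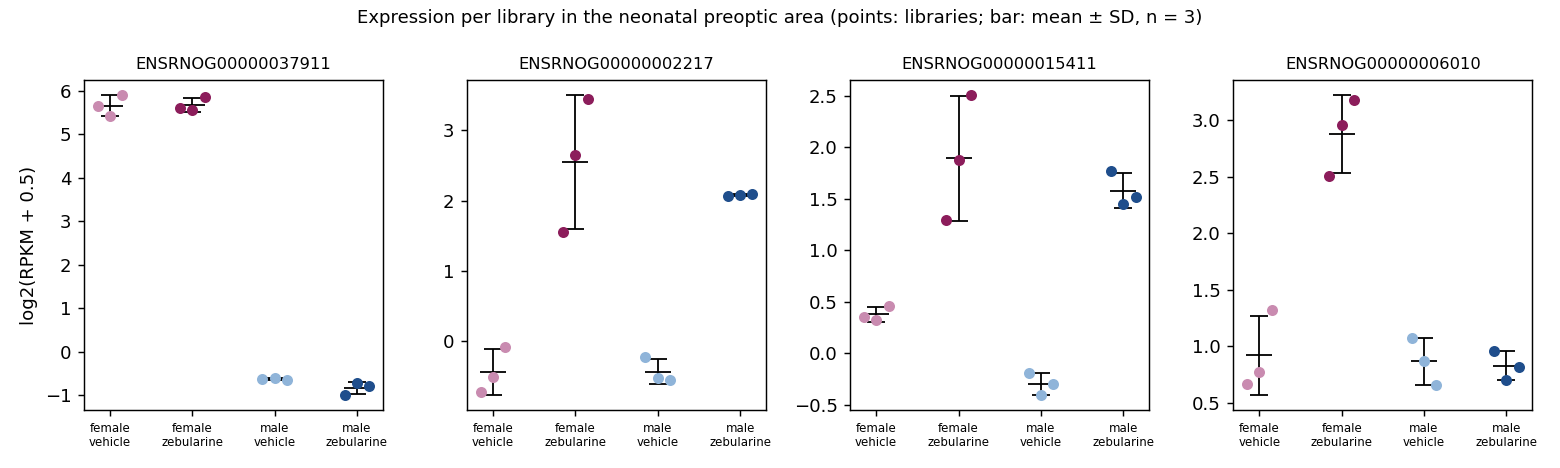
Expression of 4 genes in each of the 12 libraries, as log2(RPKM + 0.5) on the vertical axis, by sex and treatment on the horizontal axis; points are libraries and bars are the mean ± SD (n = 3). ENSRNOG00000037911 separates the sexes, ENSRNOG00000002217 and ENSRNOG00000015411 are higher under zebularine in both sexes, and ENSRNOG00000006010 is higher in treated females.

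Over all tested genes, 234 were higher in the 3 treated than in the 3 vehicle libraries of each sex without overlap, and 35 were lower, where chance would give 40.8 in each direction. Among the 65 called genes the change was upward in each sex for 64, which their choice on the average of both sexes largely fixes. The fold was larger in females for 51 of the 65 genes, and for 33 without zebularine female replicate 3. The median female log2 change of the 65 genes was 0.98 with that library and 0.78 without it, against 0.79 in males. The upward share depended on expression level: among genes with an unadjusted limma p under 0.05 with the genes ranked by mean RPKM and divided into 4 equal classes, it was 78.2% in the lowest class, 75.7% and 60.0% in the next classes, and 36.9% in the highest. No gene went from under 0.1 RPKM in all 6 vehicle libraries to at least 0.5 RPKM in all 6 treated libraries, and none went the opposite way. The count of 66 rested on the full set of libraries. It was 12, 35 and 16 without vehicle female replicates 1, 2 and 3, 113, 15 and 84 without zebularine female replicates 1, 2 and 3, 13, 15 and 12 without vehicle male replicates 1, 2 and 3, and 11, 13 and 21 without zebularine male replicates 1, 2 and 3, with at least 92.3% of the calls upward in each.

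**Figure D2:**
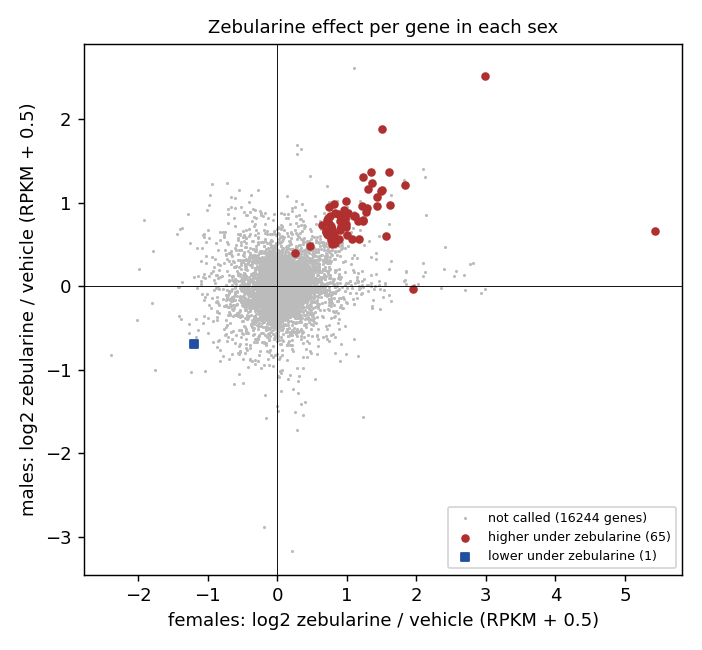
Each point is 1 of the 16310 tested genes, with its log2 zebularine to vehicle ratio (RPKM + 0.5) in females on the horizontal axis and in males on the vertical axis. The 65 genes higher under zebularine over both sexes are red circles, and the 1 lower gene is a blue square; the axes have different ranges.

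Within females, 7 genes were higher under zebularine and none was lower. All 7 were among the 65 genes above, with which this comparison shares its libraries. ENSRNOG00000006010 rose from 1.43 ± 0.494 to 6.99 ± 1.71 RPKM (SD, n = 3), a log2 change of 1.96 ± 0.21 (SE, limma adjusted p = 0.0223), while its level was 1.34 ± 0.262 RPKM in vehicle males and 1.28 ± 0.158 RPKM in zebularine males (SD, n = 3). ENSRNOG00000024382 rose from 1.42 ± 0.296 to 4.41 ± 1.02 RPKM (SD, n = 3), a log2 change of 1.35 ± 0.16 (SE, limma adjusted p = 0.0290). Of the 7 genes, 6 were also higher in treated males and 5 had an unadjusted limma p under 0.05 there. At an unadjusted p under 0.05, limma counted 657 higher and 224 lower genes in females. The count of 7 moved by over 1.5 times without any 1 library: it was 0, 1 and 2 without vehicle female replicates 1, 2 and 3, 57, 0 and 4 without zebularine female replicates 1, 2 and 3, 1, 2 and 1 without vehicle male replicates 1, 2 and 3, and 0 without each zebularine male library. The 1 gene without vehicle female replicate 2 was not among the 7, and 3 of the 4 without zebularine female replicate 3 were. Limma-voom on recovered reads called 1 of the 7 and equal depth 2 of them. With only the 2 female groups in the fit, 1 gene passed, which was lower and not among the 7.

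Within males, no gene passed by limma, and 676 were higher and 560 lower at an unadjusted p under 0.05, 7.58% of those tested. The smallest adjusted p was 0.0526, for ENSRNOG00000024382, whose level was 1.11 ± 0.0696 RPKM in vehicle males and 3.65 ± 0.310 RPKM in zebularine males (SD, n = 3). Its log2 change in males, 1.36 ± 0.16 (SE), was close to its change in females. ENSRNOG00000015411 had a male log2 change of 1.88 ± 0.24 (SE, limma adjusted p = 0.0785). Limma-voom on recovered reads also counted 0 genes in males. Limma counted 15 genes, all higher, without zebularine female replicate 3, 4 without zebularine female replicate 1, 1 without vehicle female replicate 3, and 4 with only the 2 male groups in the fit. Leaving out female libraries does not alter the male log2 changes, so these counts differ only through the spread estimated over the groups. ENSRNOG00000024382 kept its male log2 change of 1.36 without zebularine female replicate 3, where it passed (limma adjusted p = 0.00679).

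Whether the sexes responded differently was tested directly. No gene passed by limma or by limma-voom on recovered reads (smallest limma adjusted p = 0.495). At an unadjusted p under 0.05, limma counted 661 genes, 4.05% of those tested, below the share of 0.05 that chance gives. The smallest p was that of ENSRNOG00000006010, with a 95% interval of the male minus female difference from -2.65 to -1.35 on the log2 scale. Its response passed in females, and the difference of that response between the sexes did not pass. ENSRNOG00000015550 spanned a wide range: its treated females stood at 156, 177 and 543 RPKM and its vehicle females at 1.86, 4.86 and 14.2 RPKM, while the 6 male libraries lay between 0.749 and 6.10 RPKM. The male minus female difference of its zebularine effect was -4.78 ± 1.00 (SE, limma adjusted p = 0.976). For a gene of median precision the 95% interval of the difference reached 1.28-fold to either side. Over all tested genes the female and male effects, which share no library, correlated at r = 0.18 and rho = 0.13 across genes, which are not independent replicates. Of the 84 genes with an unadjusted limma p under 0.001 in females, 77 had the same sign in males, and of the 33 such genes in males, 31 had the same sign in females. No gene passed in both sexes. Without zebularine female replicate 3 the correlation was 0.090.

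Under zebularine, 5 genes were higher in females than in males and none was higher in males. ENSRNOG00000037911 and ENSRNOG00000006186, the 2 genes that differed under vehicle, differed again. ENSRNOG00000037911 stood at 51.1 ± 6.15 RPKM in treated females and 0.0619 ± 0.0552 RPKM in treated males (SD, n = 3), a log2 difference of -6.52 ± 0.13 (SE, limma adjusted p = 4.02e-10), with between 0 and 2 reads in each treated male library. ENSRNOG00000006186 stood at 60.8 ± 1.99 and 40.4 ± 1.22 RPKM (SD, n = 3), a log2 difference of -0.58 ± 0.06 (SE, limma adjusted p = 0.00381). ENSRNOG00000006010 and ENSRNOG00000015550 were also among the 5, and neither passed under vehicle. Their log2 differences under zebularine were -2.05 ± 0.21 and -6.37 ± 0.71 (SE, limma adjusted p = 0.00473 and 0.00841). At an unadjusted p under 0.05, limma counted 725 genes with male higher and 1080 with female higher, 11.1% of those tested. With array weights 1 gene was higher in males, ENSRNOG00000035330 (limma adjusted p = 0.0368, against 0.192 without weights and up to 0.662 over the alternatives). It rested on between 3 and 5 reads per treated female library and between 6 and 15 per treated male library. The count was 18 without zebularine female replicate 1, 3 without zebularine male replicate 2 or 3, 3 with limma-voom on recovered reads, and 1 with only the treated groups in the fit, where ENSRNOG00000006186 did not pass (limma adjusted p = 0.0738, from 0.00174 to 0.283 over the alternatives).

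Treated females were also set against vehicle males, to see how far females given zebularine stood from untreated males. All 18 genes that passed were higher in treated females. Of these, 14 were among the 65 genes that rose over both sexes, a comparison that holds the same 6 libraries, so that some sharing is built in. ENSRNOG00000015550 had the largest log2 difference, 7.03 ± 0.71 (SE, limma adjusted p = 0.00317), and ENSRNOG00000037911 the next among genes without overlap, 6.31 ± 0.13 (SE, limma adjusted p = 5.71e-10). At an unadjusted p under 0.05, 893 genes were higher and 203 lower, 6.72% of those tested. The count was 107 without zebularine female replicate 1, 7 without zebularine female replicate 2, 7 without each vehicle male library, 11 without zebularine male replicate 2, and 34 with limma-voom on recovered reads.

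Whether zebularine moved female expression toward the male pattern was examined by correlating the female zebularine effect with the male minus female difference under vehicle. Of the 2 genes that differed by sex, 1 moved toward the male level in treated females and 1 away from it, and neither change passed: ENSRNOG00000006186 had a zebularine log2 change of -0.05 ± 0.06 (SE) in females and ENSRNOG00000037911 one of 0.02 ± 0.13 (SE). Across all tested genes r was 0.21 and rho 0.30. Both quantities contain the same 3 vehicle female libraries, and simulations of unchanged groups against shared controls gave a mean r of 0.50, with a central 95% range from 0.47 to 0.53. The observed covariance of 0.009997 lay below the simulated 0.0197, whose central 95% range was 0.0182 to 0.0213, a difference of -0.00970. It also lay below 0.0236, simulated with each gene's residual SD, and 0.0202, computed from the spread of the vehicle female libraries alone. The simulations draw genes independently, so their ranges are narrower than libraries with shared structure would give. With 3 controls, no split leaves 2 libraries on each side.

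Zebularine female replicate 3 stood apart from the other libraries. On the first principal component, with 23.4% of the variance, it scored 50.4, and the other 11 libraries lay between -11.6 and 9.49. It had 501 genes at least 2-fold above the mean of the other zebularine female libraries and 188 at least 2-fold below. The counts above and below were 168 and 249 for replicate 1 of that group, and 98 and 165 for replicate 2. Of the 65 genes that rose over both sexes, 63 were higher in it than the mean of the other zebularine female libraries, by a median of 0.60 on the log2 scale, where the median over all tested genes was 0.023. This library was among those on which the 65 genes were called, so a high value in it helped to choose them.

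**Figure D3:**
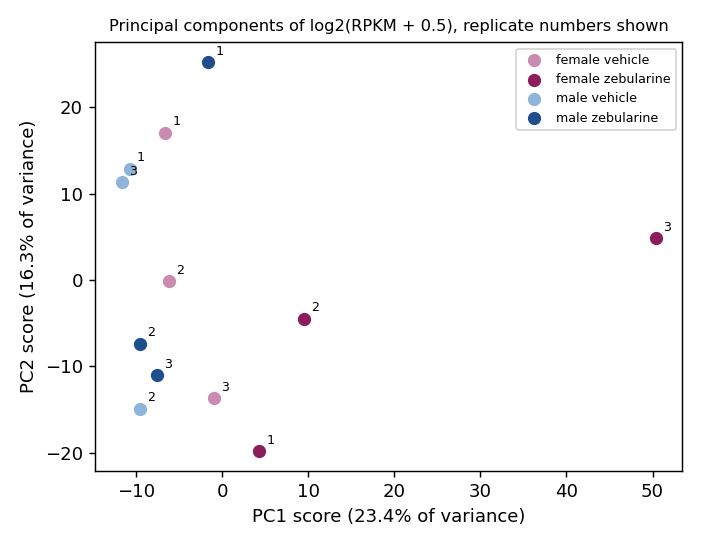
Scores of the 12 libraries on the first 2 principal components of log2(RPKM + 0.5) over the 16310 tested genes, coloured by group and numbered by replicate. Zebularine female replicate 3 lies at 50.4 on the first component, and the other libraries lie between -11.6 and 9.49.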

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

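Among the named genes, a single gene was picked out because its treated libraries moved oppositely in the 2 sexes, without overlap in either. The other tested genes were not screened for this. The gene had been named for a small p of its difference between the sexes, which partly fixes the opposite movement. ENSRNOG00000034884 had a zebularine log2 change of -1.06 in females and 0.61 in males, with no overlap of treated and vehicle libraries in either sex. The male minus female difference was 1.68 (limma unadjusted p = 0.000242). It did not pass over all genes (limma adjusted p = 0.976) or under any alternative run, where the adjusted p lay between 0.298 and 1.00. It rested on between 3 and 12 reads per library. No outlier test of single libraries was run for this gene in its groups of 3, beyond the fits that left out each library in turn. ENSRNOG00000035751 also changed in opposite directions, by -0.56 in females and 0.39 in males, on between 31 and 79 reads per library. It overlapped in males, at 30.25 RPKM treated against 30.28 RPKM vehicle. Its difference between the sexes did not pass either (limma unadjusted p = 6.57e-05, adjusted p = 0.536). ENSRNOG00000035330 changed by -0.82 and 0.55, with overlap in males.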

How the results depend on the processing

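Limma-voom on recovered reads, equal depth, removal of the length trend and the residual component were chosen after seeing the data. Gene set tests were not run, because no identifier had a symbol, and limma-trend in place of a count test was already the test used. For zebularine over both sexes the count of 66 was 9 with the replicate block and 6 with the block on the file-name number, 102 with the first residual component and 106 at an adjusted p of 0.10. It stayed within 1.5 times in the other 12 alternatives and ran from 11 to 113 when 1 library was left out. Among those 12, the fit with only the compared groups holds all 4 groups here, so it repeats the main fit and tests nothing. The same-numbered libraries did not pair throughout: their deviations correlated at between -0.30 and 0.30 over 18 pairs, 5 of them over 0.1. On average r was -0.0021, and 4 of 12 libraries correlated best with their own number. Vehicle female, vehicle male and zebularine male replicate 1 did vary together (r = 0.20, 0.30 and 0.16). Zebularine female replicate 1 went against them (r = -0.17, -0.11 and -0.30). Pairs with the same file-name number averaged -0.013, with 2 of 12 over 0.1. Each block also removes degrees of freedom. Whether calls were lost to that or to shared deviations was not tested, so a lost call is not read as a weaker effect. In treated females the count of 7 was 4 with a pseudocount of 0.1, 1 with the replicate block, not among the 7, 2 with the file-name block, 1 of them among the 7, 1 with only the compared groups, a lower gene not among the 7, 1 with limma-voom, 2 at equal depth, 31 with the residual component and 19 at an adjusted p of 0.10, and from 0 to 57 with 1 library left out. With no filter on low values 6 genes passed, 4 higher and 2 lower, and 3 were among the 7. In males the count of 0 was 2 with a pseudocount of 0.1, 4 with array weights, 4 with only the compared groups, 9 with the residual component and 2 at an adjusted p of 0.10, and from 0 to 15 with 1 library left out. The sex difference under vehicle, 2 genes, gave 5 with no filter on low values, 1 of them higher in males, 3 with the replicate block, 1 of them higher in males, 1 with the file-name block and 1 with only the compared groups, and 2 with each library left out. Under zebularine, 5 genes became 7 with array weights, 1 of them higher in males, 3 with the replicate block, 2 with the file-name block, 1 of them among the 5, 1 with only the compared groups and 3 with limma-voom, and from 3 to 18 with 1 library left out. Treated females against vehicle males, 18 genes, gave 61 with array weights, 9 with the replicate block, 2 with the file-name block, 3 with only the compared groups, 34 with limma-voom, 98 with the residual component and 55 at an adjusted p of 0.10, and from 7 to 107 with 1 library left out. The difference between the sexes, 0 genes, gave 2 with no filter on low values and 0 with each library left out. Genes called in both sexes, 0, were 1 with a pseudocount of 0.1, 3 with array weights, 9 with the residual component and 2 at an adjusted p of 0.10, and from 0 to 4 with 1 library left out. The correlation of female and male effects, 0.18, was 0.10 with the file-name block and 0.15 at equal depth, and from 0.090 to 0.20 with 1 library left out. The correlation of the female effect with the sex difference, 0.21, ran from 0.14 to 0.37. Fewer libraries or groups in a fit leave fewer degrees of freedom for the spread, yet some of these fits called more genes. A fit without libraries from outside a comparison keeps its log2 changes, so such shifts come only from the estimated spread and its degrees of freedom. The cause of the other shifts was not tested. Over 25 named gene results, no direction reversed, 44 values lost the threshold, 14 gained it and 617 did neither. These results were picked for a small p or a large change in the same data, which makes a reversal unlikely. Many fits also repeat the same log2 change, because the library left out lay outside the comparison. Only results that passed in the main fit could lose the threshold. The tally is therefore not read as a measure of how stable the results are. Library depth limits the lowest genes most: at the median gene length 1 read is worth between 0.0144 and 0.0277 RPKM.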

Other observations

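Tests of scaling, of shared variation and of a single library were chosen after the results they bear on were seen; for the test on genes picked without that library, the bounds were set before its own value was seen. A group of 32 genes was higher in treated females than in treated males at an unadjusted limma p under 0.001, without a sex difference under vehicle at an unadjusted p under 0.05, while 8 genes were higher in males on the same terms. Their median male minus female difference was -1.55 on the log2 scale under zebularine and -0.13 under vehicle. The median zebularine minus vehicle difference of the 32 genes was 1.48 in females and -0.04 in males. The choice of these genes fixes part of that contrast. All 32 were higher in each of the 3 treated females than in each of the 3 treated males, which follows in part from how they were picked. Their medians over the mean of the treated males were 0.90, 1.43 and 2.31 in treated female replicates 1, 2 and 3.

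Without zebularine female replicate 3, 80.0% of the median difference of these 32 genes was left, but picking them with all 3 treated females largely fixes that value. Picked by the same rule without that library, 40 genes were higher in females, 21 of them among the 32, and 13 were higher in males, which argues against that library as the whole cause. The 32 genes varied together in the 6 vehicle libraries. Those libraries entered the choice of genes through the exclusion by sex and through the spread estimated over all groups, but not through the contrast itself. The mean pairwise correlation of the 32 genes after centring by sex was 0.34. It lay above 100% of 10000 lists matched on mean expression, whose central 95% reached 0.15. The central 95% of lists matched on both the mean and the vehicle SD also reached 0.15. A varying share of another tissue or cell type in the dissected samples may therefore account for them, and a program that these cells regulate together would look alike. Without symbols, no marker list could be used to tell these apart, and a response of females to zebularine stays open as a hypothesis.

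The nearly one-sided direction of the zebularine calls over both sexes was kept in each technical test. Upward calls made up 98.1% of 53 calls after thinning every library to equal depth, 98.3% of 60 calls after removal of the length trend, and 95.7% of 70 calls under the less favourable of quantile normalization and equal medians. These values argue against depth, length and scaling as the whole cause. Of 100 splits that reassigned treatment within each sex, the real one included, 1 gave as many genes as the real 66. The highest other gave 23. This argues against a chance assignment of the libraries as the source of this count. It does not show that the libraries are independent animals, which the labels do not say. No biological explanation was tested.

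Zebularine female replicate 3 was still the most extreme library on the first component after thinning, by 3.99 times the next, which argues against depth. Its deviation from the other treated female libraries correlated with the zebularine effect in males, which shares no library with it, at r = 0.19 across genes, between the bounds of 0.1 and 0.2 set for the test, and at rho = 0.28, above them. A stronger response to zebularine in that library may be part of its distance. It cannot be told apart from other sources, because the bounds were set for r, which does not decide, and the rank correlation goes with that explanation. Other differences in dissection or RNA were not tested.

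For the sex difference under vehicle, 1 of 10 splits gave as many genes as the real 2, with 1 in the highest other split. For zebularine in females, 1 of 10 gave as many as the real 7, with 1 in the highest other. For males, 10 of 10 gave as many as the real 0, with 0 in the highest other, which a real count of 0 fixes in advance. For sex under zebularine and for treated females against vehicle males, 1 of 10 gave as many as the real 5 and 18, with 0 in the highest other. These 10 splits are too few for a share under 0.05. For the difference between the sexes, 100 of 100 splits gave at least the real 0, which is again fixed in advance and tests nothing, and the highest other gave 23, in a split where 1 female and 2 male libraries were moved, so that treated and vehicle libraries of the sexes were partly exchanged.

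Movement of female expression toward the male pattern was tested as a hypothesis, and the test did not find it. The covariance of 0.009997 lay below the range from 0.0182 to 0.0213 that shared controls alone gave. It also lay below the value expected from the pooled spread in each of the 9 fits that left out 1 of the libraries it is computed from. Simulated unchanged groups did not reach values this low within that range either, so they do not match these libraries in full. The test therefore does not exclude movement.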
